A study of Mus musculus with 3 samples.

How the data were processed

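Total RNA of posterior frontal sutures was amplified, labelled with Cy3 and hybridised to 1 Agilent array per group, per the labels' protocols. The 3 groups were P5 wild type, P7 wild type and P7 Runx2+/-, taken from the labels, with 1 array each. All arrays lay on 1 slide and were scanned on 1 date, so no batch could be tested. Images were read with Agilent Feature Extraction, version 10.7.1.1 per the file headers and version 9.5.1.1 per the submitters' processing notes. The authors deposited the processed signal, an intensity on a linear scale that the software had corrected for background and spatial trend, per the file headers. The same files hold each spot's mean and background intensity, a processed error and flags. A table of the authors' processed intensity values was deposited too. Its columns have medians of 12.59 each and agree in sorted order to within 0.001 log2 units, as quantile normalization leaves them. They ranked probes almost as the scanner did (rank correlations 0.99999, 0.9999 and 0.99997). The steps behind that table are not given in the sources used here, and its values served only as an alternative.

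Control spots and spots that the software called outliers were left out, and spots of the same probe were averaged on the log2 scale, which left 55680 probes. Each array's 75th percentile was subtracted from its log2 values. A probe not well above background on an array took the higher of its own value and the lowest value of any probe that was. These floors lay at -2.12, -0.78 and -3.25 log2 units on the P5 wild-type, P7 wild-type and Runx2+/- arrays. No spot was saturated. A gene was represented by its brightest probe. A difference was taken where the gene was well above background on both arrays. Where it was so on a single array, the difference was a lower bound, written as at least N-fold, and was kept only if that array was the higher. All other genes have no order and were left out of counts and list medians, which is stricter than the planned wording and was adopted once the floors were seen to differ between arrays. A difference of at least 2-fold was counted.

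Probes were named through their RefSeq accession for 27234 probes, using names of the GRCm38.p6 annotation, of which 2838 received a newer symbol. The others kept the name in the files, and 2744 carried only a probe identifier. Probe coordinates are those of the files, on mm9. They lie within transcripts named by the files, and the exon or untranslated region was not looked up because no annotation of that build was used here.

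The 30 gene lists, with 456 entries of which 1 had no probe, were fixed before the data were examined, as were the rule for named genes and the alternatives except those said to be added. A list member counted as measured if it was above background on at least 1 of the 3 arrays. A list's median was placed among medians of 10000 random lists of the same size, matched on deciles of mean expression, as a description of these arrays and not a test. The genes named are Runx2, a fixed panel of 24 genes, for age and genotype the 10 genes most increased and most decreased on both arrays whose probes agreed in direction, up to 4 members per list at least 1.5-fold apart, and the 5 largest lower bounds per direction. Not every gene that this rule selects is named. Further list members were named after their values were seen: Omd and Ifitm5 as exceptions to their list, Ctsk, Pdpn, Elane, Runx1, Cbfb, Rspo3, Csf1r, Sox5, Twist1 and Kdr, and the probes of Smo, Hhat and Gas1. Mpo, Cebpe, Acan, Col11a2 and the other probes of Fgfr1, Tcf7l2, Sox5 and Cdon were added in the same way.

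The precision of a value is limited by the number of arrays and by signal over background. The spot SD was 0.163, 0.187 and 0.117 log2 units on the 3 arrays, from probes with at least 5 spots. It was 0.274 for the dimmest of 3 equal groups of such probes on the P7 wild-type array. The steps were tested on simulated arrays built from 35019 genes with 200 changed. For genotype, 40 of 50 genes changed 2.5-fold and 50 of 50 changed 4-fold were called, 0 of 50 changed 1.5-fold were called, and 1 unchanged gene was called. The simulated arrays shared 1 profile and carried 1 spot SD per array. Changed genes were drawn from those above background on all arrays. Variation between samples, a trend with brightness and a slope along transcripts were left out. These counts therefore check the steps and give no error rate for the real calls.

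The alternatives fixed at that stage were quantile normalization, cyclic loess, scaling to the median of probes detected on all arrays, normexp background correction (offset 50) followed by the 75th percentile, a stricter and no filter on dim probes, no floor, the mean over a gene's probes, the authors' values, leaving out saturated probes, and thresholds of 1.5-fold and 3-fold. Chosen after seeing the data were the 75th percentile of probes detected on all arrays, normexp with median scaling, the probe nearest the 3′ end, leaving out the X and Y chromosomes, and keeping genes whose mean over the arrays was at least 4 times the highest floor. The last replaced a filter on the lower of the 2 arrays, because a filter on a minimum favours a direction. Normexp with median scaling was added once plain normexp had turned the split of calls. Without a filter on dim probes the floor has to go too, so that alternative changes 2 choices. At most 47.33% of the probes were detected on an array, which is why the percentile over detected probes was added. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.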

Results

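Gene expression in the posterior frontal suture of the mouse, the midline cranial suture between the frontal bones, was measured on 3 one-colour Agilent whole-genome arrays. The tissue came from C57BL/6 wild-type mice at postnatal days 5 and 7 and from Runx2+/- mice at day 7, with 1 array for each group. Runx2 is the transcription factor required for osteoblast differentiation, and Runx2+/- mice carry 1 functional copy of the gene. The labels do not say how many mice gave the RNA of an array. No group has a replicate, so every difference below is between 2 hybridised samples, has no replicate check and has no p-value. The only error available is technical. From probes spotted repeatedly on an array, the SD of a log2 difference between arrays was 0.25 for P7 against P5 wild type, 0.22 for P7 Runx2+/- against P7 wild type and 0.20 for P7 Runx2+/- against P5 wild type. Different probes of the same gene disagreed more, with a root-mean-square SD of 0.46, 0.56 and 0.70 for these comparisons.

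The arrays differed in brightness. Of 55680 probes, 22316 (40.08%) were well above background on the P5 wild-type array, 16257 (29.2%) on the P7 wild-type array and 26352 (47.33%) on the Runx2+/- array. The 75th percentile of the processed signal was 52.1, 22.8 and 124.3 intensity units, respectively. Dim genes leaned lower on the Runx2+/- than on the P7 wild-type array. Among probes well above background on both, the dimmest of 8 equal groups had a median log2 difference of -0.70. The next group had 0.12 and the brightest -0.09. The scanner software marked the P7 wild-type array for evaluation because its replicate probes varied by a median of 8.10%. The Runx2+/- array was the brightest for mouse probes, yet its spiked-in control transcripts lay a median of 1.60 log2 units below those of the P5 wild-type array. A sign of RNA quality also differed. Within transcripts that had several probes, the log2 difference of P7 Runx2+/- minus P7 wild type rose by a median of 0.14 per kb towards the 3′ end (bootstrap 95% interval 0.11 to 0.18, 775 transcripts). The same slope was 0.20 for P7 minus P5 wild type and 0.38 for P7 Runx2+/- minus P5 wild type.

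Runx2 itself was measured with its brightest probe (chromosome 17, 44951128 to 44951187, minus strand, mm9) at 2.38 on the P5 wild-type array, 1.46 on the P7 wild-type array and 1.08 on the Runx2+/- array, in log2 units above the array's 75th percentile. The Runx2+/- value was therefore 0.38 below the P7 wild-type value, a 1.30-fold difference, and the P7 wild-type value was 0.92 below the P5 value. This probe lay nearest the 5′ end of the Runx2 probes, and within transcripts the differences rose towards the 3′ end in all 3 comparisons. Whether that slope lowered the Runx2 differences was not tested. The other probes of Runx2 did not give one direction. A probe at 44744925 to 44744984 was well above background on the P5 wild-type and Runx2+/- arrays only, and a probe at 44633034 to 44633093 on the Runx2+/- array only. With the probe nearest the 3′ end, Runx2 was at least 0.74 higher on the Runx2+/- than on the P5 wild-type array. The labels do not say which part of the gene the allele lacks, so these probes do not check the genotype label. Of the other Runx family genes, Runx1 was 0.73 lower on the Runx2+/- than on the P7 wild-type array and its partner Cbfb was 0.23 higher, while Runx3 was not well above background on any array. The list median of the 3 measured members was -0.66 for age, at percentile 2.83 of random lists matched on expression, and -0.38 for genotype, at percentile 12.93. It turned to 0.22 and 0.23 with the probe nearest the 3′ end.

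The first comparison asked what distinguished the suture at P7 from P5 in wild-type mice. Neutrophil genes were much lower on the P7 array, while most bone and matrix genes lay within 2-fold, with list medians above 0. Of 17 osteoblast genes, 16 lay within 2-fold, 14 were above 0 and 3 below, with a median log2 difference of 0.61 (member SD 0.59). The median lay at percentile 100 of 10000 expression-matched random lists, whose central 95% ran from -0.27 to 0.26. Col1a1, the main collagen of bone, was 0.66 higher, Bglap2 (osteocalcin) was 0.74 higher and Alpl (alkaline phosphatase) was 0.69 higher. Spp1 (osteopontin), Ifitm5 and Omd were lower, by 0.84, 0.78 and 0.75. The osteoblast median became -0.06 after normexp background correction, which moved the median of all probes above background on both arrays to -0.25.

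Among 5 measured osteocyte genes the age median was 0.49 (percentile 94.96), led by Dmp1 at 1.22. Among 12 ordered osteoclast genes it was 0.77 (percentile 99.99), with Atp6v0d2, Dcstamp and Acp5 at 1.37, 1.18 and 1.10. Chondrocyte genes had a median of 0.54 (percentile 99.77, 11 genes), with Col9a2 and Col2a1 at 1.66 and 1.34. The 3 measured hypertrophic chondrocyte genes had a median of 0.54 (percentile 91.48), with Mmp13 at 1.26, and Col10a1 was not well above background on any array. After normexp these medians were 0.01 for osteocyte, 0.10 for osteoclast, 0.05 for chondrocyte and 0.13 for hypertrophic chondrocyte genes. Fibrous matrix genes had a median of 0.61 (percentile 100, 16 genes, of which 13 lay within 2-fold), which became -0.16 after normexp. In that list Eln (elastin) was 4.93-fold higher and Tnc (tenascin C) was 1.12 log2 units lower. Suture mesenchyme and cranial transcription factors had a median of 0.28 (percentile 96.24), with Zic1 at 1.0, and this became -0.17 after normexp. Tendon genes had a median of 0.18 (percentile 74.47), and -0.22 after normexp.

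The next lists were drawn up knowing that the study's title names hedgehog, Fgf, Wnt and Pthlh genes, so they are not independent evidence. Hedgehog genes had an age median of 0.40 (percentile 98.74, 14 genes). Gli1, a transcriptional target of the pathway, was 0.82 higher, Ihh was 0.54 higher and Ptch1 was 0.02 lower. Wnt ligands, receptors and modulators had a median of 0.38 (percentile 99.80, 27 genes), with the secreted inhibitor Sfrp2 at 1.25. Wnt nuclear factors and targets had a median of 0.04 (percentile 50.48). Tcf7 was 0.53 lower, Lef1 was at least 1.75-fold lower because it was not well above background on the P7 wild-type array, and Tcf7l2 was 1.06 higher. Another Tcf7l2 probe, above background on each array, was 0.54 lower. Fgf ligands and receptors had a median of 0.16 (percentile 71.56), with Fgfr3 at 0.86, Fgfr1 at -0.06, Fgfr2 at 0.07 and Fgf18 at -0.93. Other Fgfr1 probes, dimmer but above background on each array, gave 1.16 and 0.85. Fgf feedback targets had a median of 0.15 (percentile 62.91), and none was 2-fold apart. The last 3 medians turned negative after normexp, at -0.04, -0.05 and -0.26, and those of hedgehog genes and Wnt ligands, receptors and modulators fell to 0.04 and 0.05. Pthlh, the secreted parathyroid hormone-related peptide, was well above background on the P7 wild-type array only and was at least 3.71-fold higher there than at P5. Pthlh was dim there, at 19.4 intensity units before scaling, where the lowest value well above background was 13.3. A gene above background on that array alone could only be higher at P7 or have no order. Its receptor Pth1r differed by 0.11. The Pthlh list of 2 measured genes had a median of 1.0 (percentile 70.34), which became -0.04 after normexp. Bmp and Tgfb genes had a median of 0.00 (percentile 37.92), with no gene 2-fold apart in either direction among 24.

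Neutrophil genes stood apart in the other direction. Of 12 ordered genes, 10 were at least 2-fold lower at P7, with a median of -3.47 (percentile 0.00). Ltf (lactoferrin) was 21.6-fold lower, Ngp 18.2-fold, S100a8 13.2-fold and S100a9 11.9-fold lower. Elane, expressed in neutrophil precursors, was 0.74 higher. In the same list Mpo was 0.80 lower and Cebpe at least 2.15 lower. Other blood cell lists moved less. The erythroid median was -0.51 (percentile 0.43), the B cell median was -0.56 (percentile 0.73) and the macrophage median was -0.18 (percentile 7.30), although the lysozyme genes Lyz1 and Lyz2 were lower by 1.99 and 2.28. Medians of markers of neighbouring tissues were below 0. The leptomeningeal median was -0.55 (percentile 0.36), with Ptgds lower by 2.77, but 3 of its 7 genes were higher and the median was 0.16 over the 5 measured on both arrays. The neural and glial median was -0.80 (percentile 0.14), with Stmn2 and Tubb3 each lower by 2.01. Skeletal muscle had a median of -0.65 (percentile 0.91), epidermis -0.75 (percentile 0.66, 4 genes), adipocyte -0.83 (percentile 1.28, 2 genes), and immediate early and heat shock genes -0.67 (percentile 0.43). The endothelial median was 0.01 (percentile 50.51), and it lay between -0.65 and 0.03 over the alternatives. The cell cycle median was -0.23 (percentile 0.65) with no gene 2-fold apart, and the reference gene median was -0.28 (percentile 2.73). The 10 genes with the largest increases among those measured on both arrays were Iqsec3 (14.6-fold), Tmem185b (14.4-fold), Fxyd7, Eln, Pyroxd1, Fam24b, Angptl2, Tbc1d12, Scn8a and Flvcr1, the last at 4.07-fold. The 10 largest decreases were Ltf, Ngp, Slpi, Retnlg, Lcn2, S100a8, Wfdc21, S100a9, Csta2 and Stfa2l1, the last at 11.2-fold. Of genes measured on a single array, the largest bounds were for Lcp2, Abcd2, Ttr, Jade3 and Hyal3, at least 8.14-fold higher at P7, and for Ifitm6, Stmn4, Mmp8, Asprv1 and Ltb4r1, at least 6.24-fold lower.

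Over all genes with an order between the arrays (14332), 907 were at least 2-fold higher at P7 and 471 at least 2-fold lower, of which 252 and 172 were bounds. A share of 65.8% of these calls was higher. After normexp the counts were 32 higher and 937 lower, a share of 3.3%, and with normexp scaled to the median of probes detected on all arrays the share was 35.2%. With the processed signal as measured, without the floor, 950 were higher and 1461 lower. Among genes called higher that had another probe above background on both arrays, 9 of 68 had that probe at least 2-fold higher too. Among those called lower it was 13 of 47.

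**Figure D1:**
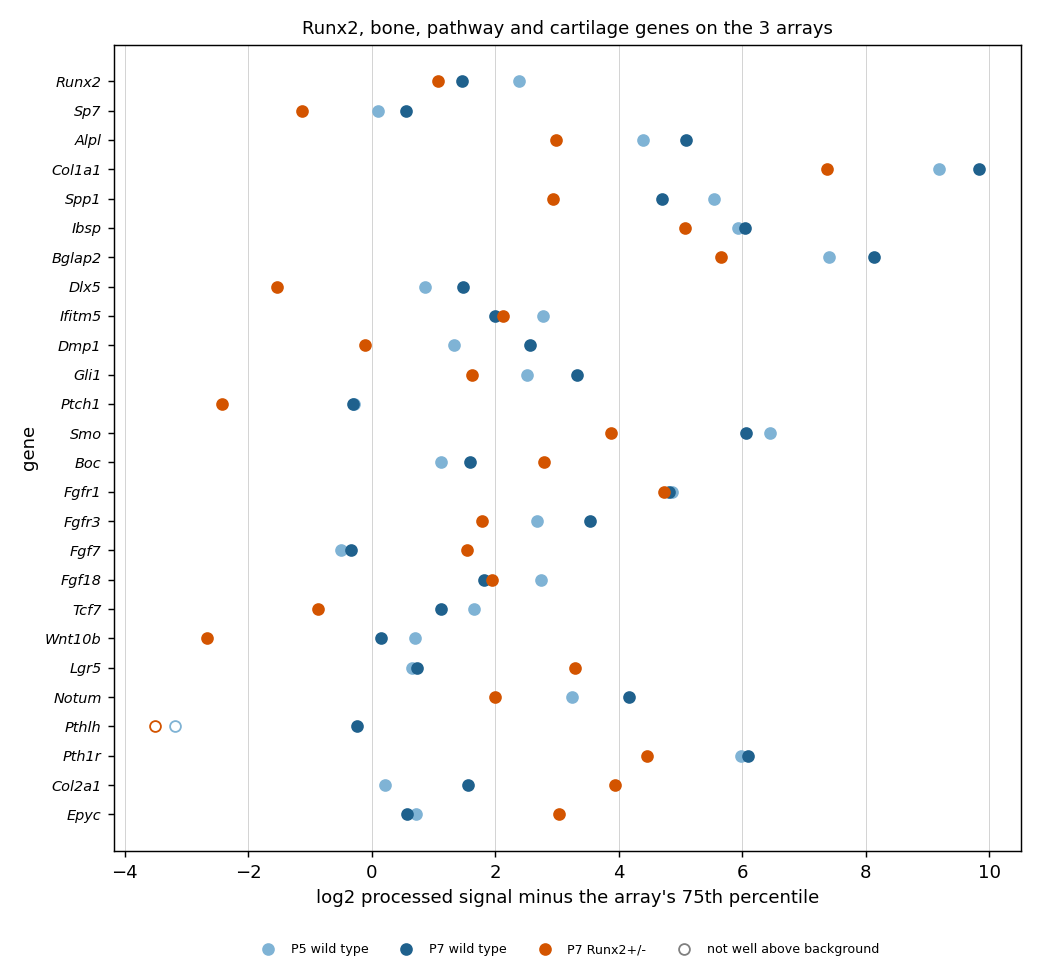
Expression of Runx2, bone, pathway and cartilage genes, 1 row per gene, on the 3 arrays. The horizontal axis is the log2 processed signal minus the array's 75th percentile, each point is 1 array, and open points were not well above background. Col1a1 lay at 9.18, 9.84 and 7.37 on the P5 wild-type, P7 wild-type and Runx2+/- arrays, and Col2a1 at 0.22, 1.56 and 3.94.

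The second comparison asked how the Runx2+/- suture differed from wild type at P7. Osteoblast genes were lower together on the Runx2+/- array. Of the 17 measured, 13 were at least 2-fold lower, none was at least 2-fold higher, and the median log2 difference was -1.77 (member SD 0.86). It lay at percentile 0.00 of random lists, whose central 95% ran from -0.40 to 0.35. The median was -0.54 after normexp and -1.25 with normexp and median scaling. Dlx5, a homeobox regulator of bone formation (chromosome 6, 6828063 to 6828122), was 8.02-fold lower. Bglap2 was lower by 2.49 and Col1a1 by 2.48 (chromosome 11, 94813115 to 94813174). The near-identical Bglap and Bglap3 were lower by 2.37 and 2.34 and cannot be counted separately from Bglap2. Alpl was lower by 2.10, Spp1 by 1.77, Sp7 (osterix) by 1.67 and Ibsp (bone sialoprotein) by 0.97. Ifitm5 was 0.12 higher. Osteocyte genes had a median of -1.90 (percentile 0.10), with Dmp1 lower by 2.66, Mepe by 2.09 and Phex by 1.90, and Pdpn 0.14 higher. Fgf23 was 1.71 lower with its used probe, while its other probe was not well above background on any array. Osteoclast genes had a median of -1.09 (percentile 0.03), with Atp6v0d2 lower by 3.45, Dcstamp by 3.12 and Mmp9 by 2.74, but Ctsk (cathepsin K) lower by 0.06. After normexp the osteoclast median was -0.14 and the osteocyte median -0.84. Hypertrophic chondrocyte genes had a median of -0.98 (percentile 3.42), with Mmp13 lower by 2.75, and of -0.52 after normexp. On the same arrays the sex-linked transcripts and the slope along transcripts differed, as given above and below.

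Most cartilage genes went the other way. Of 14 ordered chondrocyte genes, 7 were at least 2-fold higher on the Runx2+/- array and 2 at least 2-fold lower, with a median of 0.92 (percentile 100). Epyc was 2.46 higher, Col2a1 2.38 higher (chromosome 15, 97806071 to 97806130) and Cnmd at least 5.14-fold higher. Sox5, Col11a2 and Acan were lower, by 1.75, 1.51 and 0.67, and the other 11 lay above 0. The other Sox5 probes were not well above background on the P7 wild-type array. The list median was 0.46 among bright genes and 0.51 with normexp and median scaling. Tendon and ligament genes had a median of 1.11 (percentile 99.98, 4 genes), with Tnmd at 1.61. Endothelial genes had a median of 0.83 (percentile 100), with Robo4 at 1.94 and Emcn and Egfl7 at 1.61, but Kdr, the main receptor for vascular endothelial growth factor, was 1.97 lower with its brightest probe and 1.87 higher with the probe nearest the 3′ end. Macrophage genes had a median of 0.52 (percentile 97.80) and B cell genes of 0.71 (percentile 99.07), the latter turning to -0.20 with normexp and median scaling. Neutrophil genes had a median of 2.08 (percentile 100), with Camp 12.9-fold and Ltf 12.4-fold higher. Adipocyte genes had a median of 1.31 (percentile 99.98, 3 genes), with Pparg at 1.69. Fibrous matrix genes had a median of 0.01 (percentile 54.35), with Col14a1 at 1.52 and Tnc at -1.61. Suture mesenchyme and cranial transcription factors had a median of 0.09 (percentile 39.74), and of -0.06 with cyclic loess, with Twist2 1.36 higher, Foxc2 1.31 higher and Twist1 1.0 lower.

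Hedgehog genes had a genotype median of -1.15 (percentile 0.00), with 8 of 14 at least 2-fold lower and 3 at least 2-fold higher. The study's title names this pathway, so the list is not independent evidence. Gli1 (chromosome 10, 126766967 to 126767026) was lower by 1.70, Ptch1 (chromosome 13, 63612879 to 63612938) by 2.12, Hhip, a secreted antagonist, by 2.02, and Ihh by 0.98. Ptch1 was dim, at 18.5 and 23.3 intensity units before scaling on the P7 wild-type and Runx2+/- arrays. The coreceptors Boc, Cdon and Gas1 were higher by 1.20, 1.11 and 1.06. Another Cdon probe, above background on each array, was only 0.17 higher. The median depended on which probe stood for each gene. With the probe nearest the 3′ end it was 0.23, and with the brightest probes after normexp -0.38. Smo was lower by 2.18 with the probe at 29710919 to 29710978 and 0.23 higher with the probe at 29711225 to 29711284, and the probes of Hhat and Gas1 also went opposite ways.

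Fgf ligands and receptors had a genotype median of -0.76 (percentile 0.97), with 5 of 11 at least 2-fold lower and 1 at least 2-fold higher. After normexp the median was -0.08. Fgf8 was lower by 2.27, Fgf6 by 1.94 and Fgfr3 (chromosome 5, 34079649 to 34079708) by 1.75. Fgf8 was dim, at 19.0 and 21.5 intensity units before scaling on the P7 wild-type and Runx2+/- arrays. Its other probes were not well above background on any array. Fgf7 was 1.88 higher. Fgfr1 and Fgfr2 were lower by 0.07 and 0.21 and Fgf18 was 0.14 higher. Other Fgfr1 probes, dimmer but above background on each array, gave -1.24 and -0.32. Fgf feedback targets had a median of 0.32 (percentile 66.66), and of -0.23 with normexp and median scaling, with Etv4 lower by 1.55. Wnt ligands, receptors and modulators had a median of 0.04 (percentile 18.52), with 5 genes at least 2-fold lower and 3 at least 2-fold higher of 32. This median was negative with several scalings, down to -0.41. Wnt10b, a ligand that promotes bone formation, was lower by 2.81, the Wnt inactivating enzyme Notum by 2.16 and Wnt1 by 1.66. Wnt10b was dim, at 25.2 and 19.7 intensity units before scaling on the P7 wild-type and Runx2+/- arrays. The receptor Lgr5 was 2.55 higher and Rspo3, a secreted activator, 1.5 higher. Wnt nuclear factors and targets had a median of -0.01 (percentile 18.37), with Tcf7 (chromosome 11, 52066114 to 52066173) lower by 1.99 and Nkd1 1.31 higher, although Nkd1 was at least 4.57 lower with the probe nearest the 3′ end. This median became 0.43 after normexp. Lef1 and Axin2 gave no difference here, since Axin2 was not well above background on any array and Lef1 had no order. Pthlh was at least 8.11-fold lower on the Runx2+/- array, and Pth1r was lower by 1.63. The Pthlh list median was -2.33 (percentile 7.38), and -0.82 after normexp. The study's title names the Fgf, Wnt and Pthlh pathways too. Bmp and Tgfb genes had a median of 0.06 (percentile 22.58), and of -0.02 with cyclic loess, with 2 of 22 at least 2-fold lower and none at least 2-fold higher. Bmp8a was the furthest apart, at -2.05.

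Cell cycle genes had a genotype median of 0.36 (percentile 84.44) with no gene 2-fold apart, and reference genes a median of 0.31 (percentile 92.96). The erythroid median was -0.39 (percentile 9.41), and 0.59 after normexp. Skeletal muscle had a median of 0.38 (percentile 71.74), which was -0.51 with normexp and median scaling and -0.35 among bright genes. Neural and glial genes had a median of -0.82 (percentile 3.13, 5 genes), which was 0.37 without the floor, and epidermis -0.50 (percentile 26.48, 2 genes). Leptomeninges had a median of -0.14 (percentile 15.54), which was 0.89 after normexp. Immediate early and heat shock genes had a median of 0.42 (percentile 85.77), with Fosb lower by 2.33, and of -0.42 with normexp and median scaling and -0.35 among bright genes. The 10 largest increases of genes measured on both arrays were Camp, Ltf, Ngp, Chil3, Smoc1, Lgr5, Epyc, Col2a1, Pappa2 and Slc1a3, from 12.9-fold to 5.12-fold. The 10 largest decreases were 2 entries for Xist, then Iqsec3 (16.9-fold), Flt4, Elk4, Nrg3os, Zfp872, Atp6v0d2, Fmr1nb and Fxyd7, the last at 9.88-fold. Among genes measured on a single array, the largest bounds were for Eif2s3y, Ifitm6, Adgrf5, Ddx3y and Cnmd, at least 5.14-fold higher, and for Lcp2, Abcd2, Cib4, Ttr and Hyal3, at least 17.8-fold lower. Lcp2, Abcd2, Ttr and Hyal3 were also among the largest bounds for age. Both of their bounds rest on the same P7 wild-type values, so they are not separate results. The floor was -3.25 on the Runx2+/- array and -2.12 on the P5 wild-type array.

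Of 14420 genes with an order, 750 were at least 2-fold higher on the Runx2+/- array and 1988 at least 2-fold lower, so that 27.4% of the calls were higher. After normexp, which moved the median of all probes to 0.63, the counts were 4346 higher and 525 lower, a share of 89.2%. With normexp scaled to the median of probes detected on all arrays the share was 18.6%, and without the floor it was 39.9%. Among genes called lower with another probe above background on both arrays, 111 of 254 had that probe at least 2-fold lower too, and among those called higher it was 21 of 77.

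Transcripts that mark the sex of the animals differed with genotype. Xist, which is expressed from the inactive X chromosome of females, was at 2.45 and 1.94 on the P5 and P7 wild-type arrays and at -3.10 on the Runx2+/- array, 32.8-fold lower than on the P7 wild-type array (chromosome X, 100656289 to 100656348). Ddx3y and Eif2s3y, on the Y chromosome, were at 1.79 and 2.37 on the Runx2+/- array. Both were well above background on the P5 wild-type array as well, at -0.88 and -0.35, and neither was on the P7 wild-type array. The sex of the animals may thus differ in the age comparison too, although the floor of the P7 wild-type array leaves the size open. Ddx3y and Eif2s3y were at least 5.91-fold and 8.84-fold higher on the Runx2+/- than on the P7 wild-type array. The sex-linked list median was -0.47 for age (percentile 17.73) and 2.56 for genotype (percentile 99.99), the latter over members that went both ways and -5.04 where both arrays were above background, which leaves Xist. Of the 750 genes called higher for genotype, 40 (5.33%) lay on the X chromosome, and of the 1988 called lower, 67 (3.37%), against 3.55% of all genes with an order. On the Y chromosome lay 2 of those called higher and 3 of those called lower. Leaving out X and Y genes gave 708 higher and 1918 lower.

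**Figure D2:**
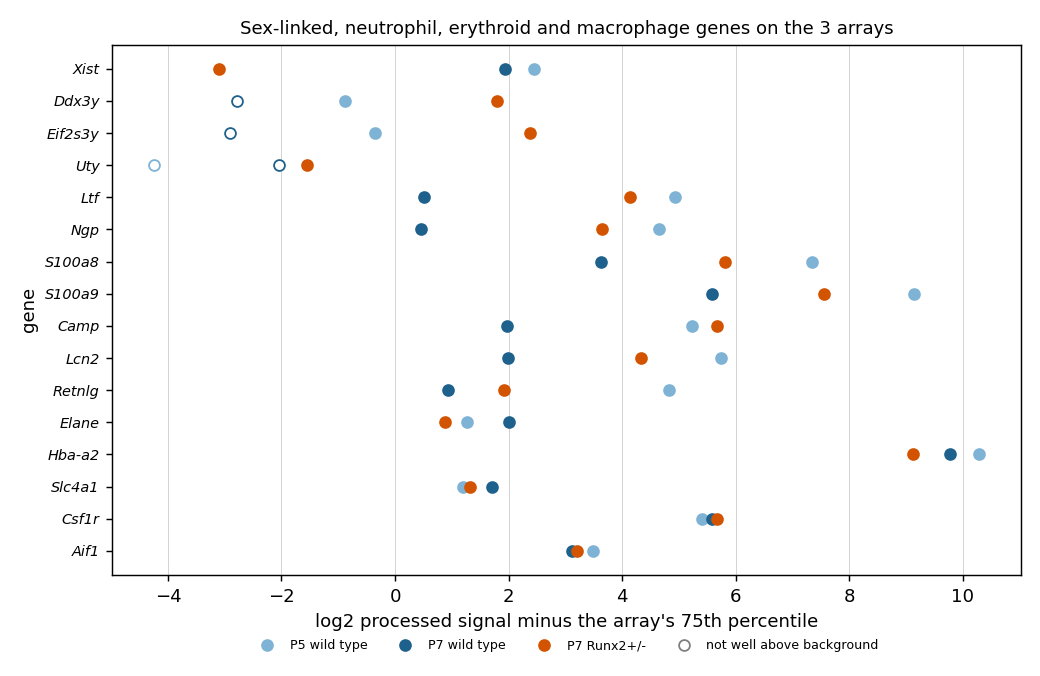
Expression of sex-linked, neutrophil, erythroid and macrophage genes on the 3 arrays, on the same log2 scale, with 1 point per array and open points for genes not well above background. Ltf lay at 4.94, 0.51 and 4.14 on the P5 wild-type, P7 wild-type and Runx2+/- arrays, while Csf1r lay at 5.40, 5.58 and 5.67.

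The Runx2+/- array was also set against the P5 wild-type array, which leaves out the dim P7 wild-type array. The Runx2+/- array is the same as in the genotype comparison, and age differs here as well as genotype, so the 2 comparisons are not independent. The slope along transcripts was also the steepest of the 3 comparisons, at 0.38 per kb. Osteoblast genes had a median of -1.31 (percentile 0.00), with 12 of 17 at least 2-fold lower and all 17 below 0. Col1a1 was lower by 1.81, Dlx5 by 2.40 and Spp1 by 2.61. Osteocyte genes had a median of -1.40 (percentile 0.21) and osteoclast genes of -0.95 (percentile 0.26). Chondrocyte genes had a median of 1.76 (percentile 100), with Col2a1 at 3.72, and fibrous matrix genes of 0.71 (percentile 100). Hedgehog genes had a median of -0.44 (percentile 1.54), which was 0.43 with the probe nearest the 3′ end. Fgf ligands and receptors had a median of -1.09 (percentile 0.20), Wnt ligands, receptors and modulators of 0.31 (percentile 88.50), and Wnt nuclear factors and targets of -0.27 (percentile 5.84). The Wnt medians turned to -0.22 with normexp and median scaling and to 0.57 among bright genes, respectively. Wnt10b was lower by 3.37, Tcf7 by 2.52 and Pth1r by 1.52, and Pthlh had no order. Neutrophil genes had a median of -0.83 (percentile 0.04), neural and glial genes of -1.75 (percentile 0.00) and endothelial genes of 0.74 (percentile 99.91). In all, 1573 of 18148 genes were at least 2-fold higher and 2788 at least 2-fold lower, a share of 36.1% higher. The share was 23.6% with scaling to the median of probes detected on all arrays, 23.4% with their 75th percentile, 69.6% after normexp and 9.7% with normexp and median scaling.

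**Figure D3:**
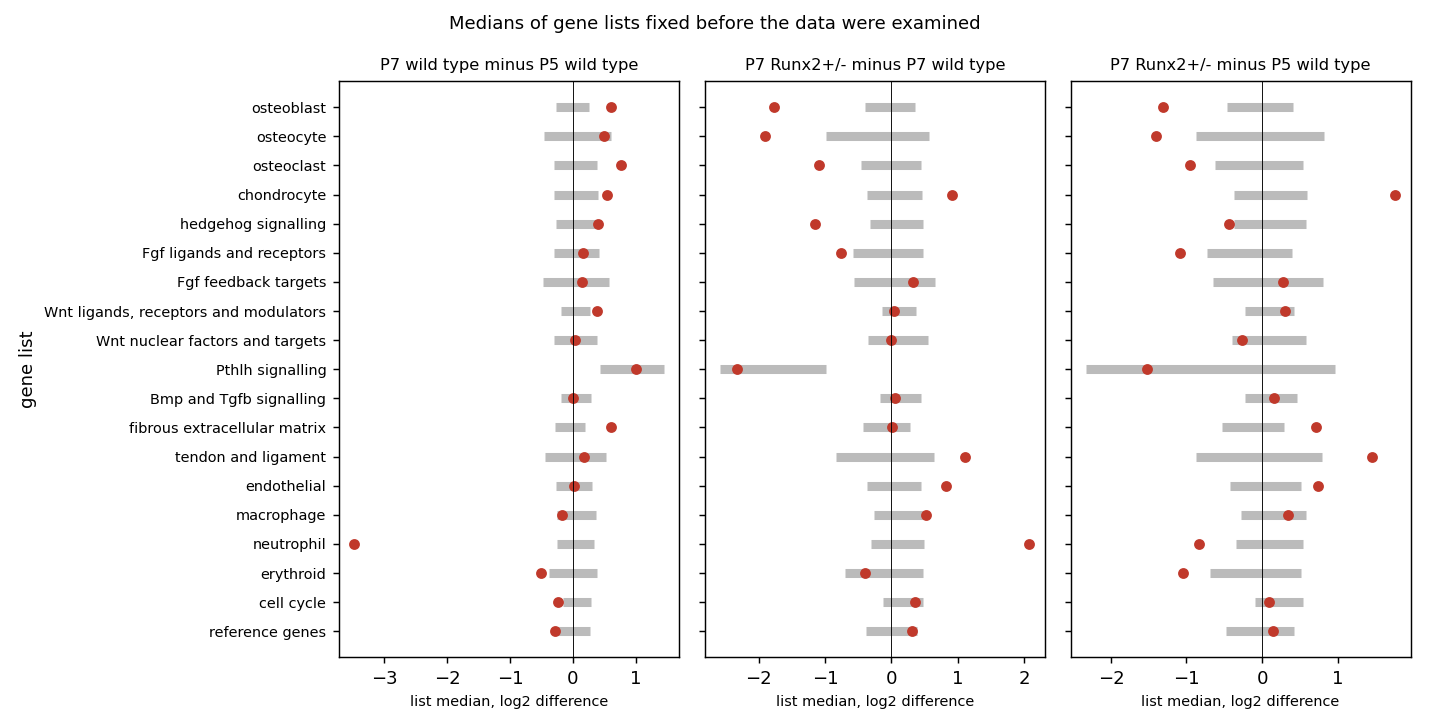
Median log2 difference of selected gene lists (red points) in the 3 comparisons, with grey bars for the central 95% of medians of 10000 random lists matched on expression. The osteoblast median was 0.61 for age, -1.77 for genotype and -1.31 for P7 Runx2+/- minus P5 wild type.

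Genes that differed with age often differed the other way with genotype. Among 13693 genes ordered in both comparisons, 601 were at least 2-fold higher at P7 and at least 2-fold lower on the Runx2+/- array, and 91 were lower at P7 and higher on the Runx2+/- array. Independent lists of these sizes would share 131.7 and 19.3 genes, but these expectations leave out the order rule. A gene above background on the P7 wild-type array alone can only be ordered as higher at P7 and lower on the Runx2+/- array. One above background on both other arrays but not on that one can only be ordered the opposite way. Part of the 601 and 91 is thus fixed by the rule. Another 41 genes were at least 2-fold apart in the same direction. Both comparisons use the P7 wild-type array, so chance alone makes them oppose each other. Over the 12838 genes above background on all 3 arrays, the correlation across genes was -0.30 and the covariance -0.137. There 349 and 53 genes were shared in the directions above, where independent lists would share 85.3 and 12.9. Simulated unchanged arrays gave a correlation of -0.63 and a covariance of -0.035, but they carry spot noise alone and no variation between samples. With 1 array per group the shared array cannot be split, so a single P7 wild-type array that stands apart could give all of this overlap.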

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

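The alternatives that were chosen after seeing the data are the 75th percentile of detected probes, normexp with median scaling, the probe nearest the 3′ end, the X and Y chromosomes left out, and the filter for bright genes. With 1 array per group no array could be left out within a group, and the only comparison without the dim P7 wild-type array, of the Runx2+/- with the P5 wild-type array, shares the Runx2+/- array and differs in age too, so it is no independent check. Signal over background limits the results most directly for genes near the floors. The osteoblast median for genotype was below 0 under each alternative run, and the neutrophil median for age likewise. Under quantile normalization, cyclic loess, the authors' values, the X and Y chromosomes left out and saturated probes left out, no count of calls moved by over 1.5 times and no named gene at least 2-fold apart turned, nor did a list median further from 0 than the technical SD. Medians nearer 0 did, with cyclic loess for example the genotype median of Wnt ligands, to -0.02. No spot was saturated, so leaving such probes out removed nothing. Apart from the list medians given below, 189 others moved by more than the technical SD and 1109 did not. Unless said otherwise, the cause was not tested.

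With normexp background correction 32 genes were higher and 937 lower for age, 4346 higher and 525 lower for genotype, and 704 lower for P7 Runx2+/- minus P5 wild type. The age medians turned to -0.06 for osteoblast, -0.17 for suture mesenchyme, -0.04 for Pthlh and -0.16 for fibrous matrix genes, and the genotype medians to 0.21 for the Runx family and 0.59 for erythroid genes. Eln turned to 0.16 for genotype. The genotype medians moved to -0.54 for osteoblast, -0.38 for hedgehog, -0.08 for Fgf ligands and receptors, 0.30 for Wnt ligands, 0.43 for Wnt nuclear factors and -0.82 for Pthlh genes, and the osteoblast median of P7 Runx2+/- minus P5 wild type to -0.77. This setting also moved the median of all probes from 0.06 to -0.25 for age, from 0.09 to 0.63 for genotype and from 0.04 to 0.14 for P7 Runx2+/- minus P5 wild type.

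With normexp and the median of probes detected on all arrays, 153 genes were higher and 282 lower for age, 478 were higher for genotype and 309 higher for P7 Runx2+/- minus P5 wild type, and 181 overlapped in opposite directions. The osteoblast median moved to 0.23 for age and -1.25 for genotype, and the neutrophil median for age to -3.06. Genotype medians were -0.41 for Wnt ligands, -0.29 for Wnt nuclear factors and -1.53 for Pthlh, and turned to -0.23 for Fgf feedback, -0.20 for B cell, -0.51 for skeletal muscle and -0.42 for immediate early genes. For P7 Runx2+/- minus P5 wild type, Fgf feedback turned to -0.10, Wnt ligands to -0.22, B cell to -0.18, Pyroxd1 to -0.16 and Tmem185b to -0.08. In that comparison 1028 genes were higher with scaling to the median of detected probes and 1021 with their 75th percentile.

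Requiring signal above background on both arrays leaves fewer genes by construction. It gave 299 genes lower for age and 402 overlapping in opposite directions. Leptomeninges turned to 0.16 for age and the sex-linked list to -5.04 for genotype, where Xist alone was left. Wnt ligands moved to -0.23 and Pthlh to -1.63 for genotype, the latter with Pth1r alone. Without a filter on dim probes and without floors, 13667 genes were higher and 1465 lower for age, 1738 higher and 16687 lower for genotype, 2747 higher and 13788 lower for P7 Runx2+/- minus P5 wild type, and 12201 overlapped. These counts take in genes below background on both arrays, whose scaled values follow the brightness of the array. Without floors alone, 1461 genes were lower for age, 1738 higher for genotype, 2620 higher for P7 Runx2+/- minus P5 wild type and 1041 overlapped. The genotype median of Fgf ligands and receptors moved to -0.48 and that of neural and glial genes turned to 0.37.

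With the mean over probes, the Runx family turned to 0.22 for age, and Gas1 to -0.23 and Nkd1 to -1.63 for genotype, the latter with a probe at the floor. With the probe nearest the 3′ end, the Runx family turned to 0.22 for age, 0.23 for genotype and 0.45 for P7 Runx2+/- minus P5 wild type, and hedgehog genes to 0.23 and 0.43 for the last 2 of these. For genotype Hhat turned to 0.47, Kdr to 1.87, Smo to 0.23 and Nkd1 to a bound of -4.57, and Fgf ligands and receptors moved to -1.09. For P7 Runx2+/- minus P5 wild type Hhat turned to 0.78, Kdr to 0.94, Smo to 0.49 and Runx2 to a bound of 0.74. The other probe alone makes these values differ, but why probes of a gene disagree was not tested.

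The threshold changes counts by construction. At 1.5-fold, 2306 genes were higher and 1629 lower for age, 2830 and 3037 for genotype, 4392 and 4534 for P7 Runx2+/- minus P5 wild type, and 1689 overlapped. At 3-fold, 318 and 123 differed for age, 102 and 1054 for genotype, 232 and 1161 for P7 Runx2+/- minus P5 wild type, and 286 overlapped. The filter for bright genes leaves 8000 genes by construction, of which 248 were higher and 138 lower for age, 301 and 855 for genotype, 521 and 805 for P7 Runx2+/- minus P5 wild type, and 170 overlapped. Genotype medians moved to -1.10 for Fgf ligands and receptors, 0.27 for Wnt ligands, 0.66 for Wnt nuclear factors and -1.63 for Pthlh, and turned to -0.35 for skeletal muscle and -0.35 for immediate early genes. Wnt nuclear factors turned to 0.57 for P7 Runx2+/- minus P5 wild type.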

Other observations

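All the tests below, their bounds and the gene families were chosen after the results were seen. The families are defined by symbol. Proteasome subunits had a genotype median of 0.39 (37 genes, 2 at least 2-fold higher), which was above 0 under each scaling run, from 0.28 to 1.31. Their age median was -0.17, below 0 under each scaling run. Subunits of oxidative phosphorylation had an age median of -0.22 (69 genes, none 2-fold apart) and a genotype median of 0.18, and neither turned under a scaling run. Cytosolic ribosomal proteins had a genotype median of -0.17, but 0.39 with quantile normalization, 0.19 with cyclic loess and 1.15 with normexp, so no direction is given. Collagens had an age median of 0.55 (30 genes, 4 at least 2-fold higher), which turned to -0.05 with normexp. For genotype 7 collagen genes were at least 2-fold higher and 6 at least 2-fold lower.

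Osteoblast genes were lower on the Runx2+/- than on the P7 wild-type array. A trend of the difference with brightness as the whole cause is argued against by the median after cyclic loess, which was -1.84. Loss of signal from the 5′ part of transcripts as the whole cause is argued against by the age comparison. Its slope along transcripts was no smaller, yet its osteoblast median was 0.61 where that slope would need -2.49. This holds only if no true rise with age offset it. Both comparisons share the P7 wild-type array, so high osteoblast values on that array alone would raise the age median and lower the genotype median. The positions of the osteoblast probes were not used, so a part of the difference may come from this loss. A smaller share of bone cells in the dissected tissue may still account for the pattern, since 6 other tissue types lay 1.10 apart between tendon and fibrous matrix, against a combined member SD of 1.03. The bound of 2 times that SD was picked after several pairings had been looked at, and a bound of 1 time the SD would have gone the other way. Genotype, sex and dissection stay open, because each group is a single array and the sex-linked transcripts differed with genotype.

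Neutrophil genes were lower on the P7 than on the P5 wild-type array and higher again on the Runx2+/- array. Dimness of the P7 wild-type array is argued against by the median after cyclic loess, which was -3.57. An equal loss of all blood or marrow cells as the whole cause is argued against by the erythroid median of -0.51, far above the neutrophil median of -3.47. The erythroid and B cell medians were low too, at percentiles 0.43 and 0.73 of random lists. A smaller or uneven loss of marrow is therefore not argued against. A different share of cells of the neutrophil lineage, age, sex and dissection stay open and were not tested.

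At 2-fold, more genes were lower than higher on the Runx2+/- than on the P7 wild-type array, with 27.4% of calls higher, against 48.2% at 1.5-fold and 8.8% at 3-fold. Genes near the detection limit as the whole cause are argued against by the bright genes, of which 26.0% of calls were higher. The choice of the brightest probe is argued against by the other probes of the genes called lower, whose median was -0.84. Background correction and scaling were tested with normexp, after which 89.2% of calls were higher. That setting also moved the median of all probes from 0.09 to 0.63. With normexp and median scaling the share was 18.6%, with quantile normalization 25.8% and with cyclic loess 20.0%. The turn came with a shift of all probes, so the test cannot tell whether this cause accounts for the split. That test at first used normexp alone, and its bound was widened to both scalings after the first value was seen.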
